A study of Homo sapiens with 13 samples.

How the data were processed

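The values used were the non-normalized summary intensities that the authors deposited for 13 Illumina BeadChip arrays, with a detection value beside each intensity, and the normalized values of the series matrix, read as log2, were used as an alternative scale. Total RNA had been isolated with a Roche kit and measured on a NanoDrop, and biotin-labelled cRNA made with an Ambion MessageAmp kit. Per the submitters' processing notes GenomeStudio 2010.2 and lumi were used, with no version for lumi and no role for either. The deposited intensities go below 0, so a background had been subtracted, and they are not normalized between arrays. The log2 values deposited by the authors have the same quantiles on all 13 arrays, with a median of 3.34. Their exact transformation is not given in the sources used here, and neither is the annotation behind the probes. The deposited detection values are named so per the file headers and are fractions between 0 and 1 that rise with the intensity, left as deposited. Per the file headers each array had 1 signal column and 1 detection column, and all columns were used.

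A pair of fraction columns had short names, 34lo and 34+41+. They were assigned by name and then checked against the deposited matrix columns, which carry sample identifiers. The rank correlation of each signal column with the matrix column of its own sample was at least 0.999995, and at most 0.904 with that of another sample. Each day and each fraction had 1 array, and the labels carry no replicate numbers. No paired analysis was possible because nothing links an array of sorted cells to an array of unsorted cells.

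Intensities were background corrected and quantile normalized over the 13 arrays jointly with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16. Detection p was taken as 1 minus the deposited detection value. Deposited median intensities ran from 8.7 to 13.4, and the lowest intensity was -28.8. The detection floor of an array, the lowest normalized level of its detected probes, ran from 5.29 to 5.73 on the log2 scale. Of 47231 probes 1 was dropped, a CDC25C probe that had no values on the 9 arrays of the time course. Symbols were matched to current names: 27035 probes carried a current symbol, 4651 an older one that was updated, 12274 a name that was not matched and 3270 none. A probe was kept in an experiment when its detection p was below 0.01 on at least 1 array of that experiment. The brightest probe was kept per gene. Genes with more than 1 probe past this filter numbered 4021 in the time course and 3665 in the fractions.

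Over days 0 to 8 each gene was fitted in limma with a natural spline of 3 degrees of freedom (splines 4.3.3), with 5 residual degrees of freedom, 3.98 prior degrees of freedom and a median residual SD of 0.248. The trend was tested with a moderated F test, and fitted changes were taken from day 0 to 4, 4 to 8 and 0 to 8. A gene passed with a Benjamini-Hochberg adjusted p below 0.05 and a fitted change of at least 2-fold. Without adjustment 8571 genes had an F test p below 0.05. In simulated data with 50 changed genes per size, a straight change from day 0 to 8 had an adjusted p below 0.05 for that interval in 10% of genes at 2-fold, 72% at 4-fold, 98% at 8-fold and 100% at 16-fold. Of the unchanged genes 14 had a trend and 13 were called changed from day 0 to 8, and the other intervals were not simulated. Nearly all of the 17657 simulated genes were unchanged, whereas 6854 had a trend in the real data. The adjusted cut-off was therefore stricter in the simulation, and the simulated shares may be too low for the real data. Differences between neighbouring days and between fractions were taken from single arrays and counted at 2-fold, with 4-fold beside it for the fractions, in genes detected on the brighter array, with the dimmer side raised to its detection floor where it was not detected. A fold change with an undetected side is printed as at least that size.

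Gene lists for 25 groups were fixed before the data were examined: pluripotency, primitive streak, early mesoderm, endothelium, arterial and Notch genes, venous genes, blood transcription factors, megakaryocyte, red cell, leukocyte, myeloid, endoderm, neural progenitor, trophoblast and surface ectoderm, mesenchyme, heart muscle, HOXA, HOXB, cell cycle, BMP targets, Nodal and activin genes, WNT targets, immediate-early and stress genes, hypoxia, and reference genes. Some lists share members, for example SOX17 in the endothelium and endoderm lists, so their tests are not independent. Symbols of 2 members were updated, for example TDGF1 to CRIPTO. A list was tested when at least 4 members were measured, which gave 72 tests over days, adjusted together. The test was camera of limma with a preset correlation of 0.01, and beside it camera with an estimated correlation and fry. In the fractions the median difference of a list was placed among 10000 random lists matched in 20 bins of expression.

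Genes were named by a rule fixed in advance. It covers CD34, ITGA2B, RUNX1 and the reference genes, the 8 largest rises and 8 largest falls of each comparison, up to 4 members with the largest changes from each list, members of a list that did not pass where the text says so, and the 10 largest transient peaks. Not every gene the rule covers is named. Clone and locus names, open reading frame names and the like were passed over. The following were chosen after the values were seen: AFP and BCL11A from day 0 to 4, HBA2 and ALAS2 from day 4 to 8, TAGLN, TWIST2, THY1 and EGLN3 from day 0 to 8, DLL4 in the fractions, the day levels of CDH5, COL1A1, COL3A1 and DCN, the genes drawn in figures, and the genes of the closing paragraphs. Among genes with several probes called, probes were called in opposite directions for 3 of 777 from day 0 to 4, 1 of 469 from day 4 to 8 and 11 of 1409 from day 0 to 8.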

Results

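Gene expression was measured on 13 Illumina bead arrays in human embryonic stem cells that were driven toward blood. The cells were a RUNX1C GFP reporter line derived from HES3, an established human embryonic stem cell line. RUNX1 is a transcription factor needed for definitive blood formation. The cells were differentiated as spin embryoid bodies, aggregates formed by centrifugation, in a defined serum-free medium. BMP4, VEGF, SCF and activin were present up to day 4, and BMP4, VEGF, SCF, FGF2 and IGF2 from day 4 on. The 1st experiment held 9 arrays of unsorted cells, 1 for each day from 0 to 8. The 2nd held 4 arrays of day 7 cells sorted on CD34, a marker of endothelium and early blood cells, and CD41, a marker of megakaryocytes and of the earliest blood cells. Between 15134 and 17833 probes were detected per array, and the number of arrays limits the precision. Each day and each fraction had 1 array, so no SD or n stands beside a level. Errors on changes over days are standard errors from a smooth curve through the 9 days, and the spread they rest on is the departure of single days from that curve.

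The course over 9 days asked which genes changed as undifferentiated cells passed through mesoderm toward endothelium and blood. Pluripotency genes fell, primitive streak genes appeared for a few days, and mesoderm, endothelial, endoderm and globin genes rose. CD34 stood at a normalized log2 level of 4.88 on day 3, 9.96 on day 5 and 11.38 on day 7. RUNX1 was highest on day 5 (6.53) against 4.71 on day 0, with a trend over days (limma adjusted p = 0.00136), and none of its 3 tested changes passed. ITGA2B, which encodes CD41, was detected on day 8 alone (5.82). In the moderated F test 6854 of 17657 genes (38.8%) had a trend over days. Of the 12 reference genes, which serve as a check of scale, only B2M, a subunit of the major histocompatibility complex class I molecule, changed from day 0 to day 8, with a rise of 1.63 ± 0.35 on the log2 scale (SE, adjusted p = 0.00944).

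**Figure D1:**
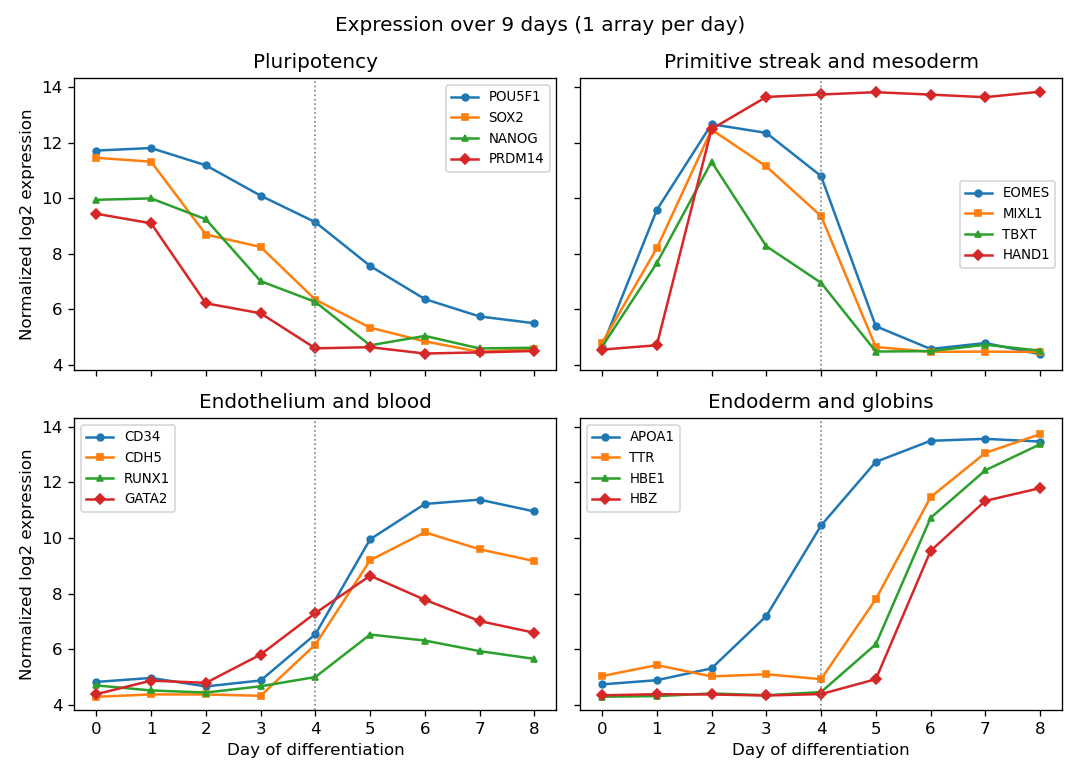
Normalized log2 expression of 16 genes on each of the 9 days in unsorted cells, 1 array per day, in 4 panels, with a dotted line at the change of medium on day 4. POU5F1 went from 11.71 on day 0 to 5.75 on day 7, EOMES peaked at 12.66 on day 2, CD34 was highest on day 7 (11.38), and HBE1 reached 13.37 on day 8.

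The largest differences between neighbouring days fell in the first 5 days. From day 4 to day 5, 1009 genes differed at least 2-fold, 687 of them higher on day 5, among them CD34 (from 6.54 to 9.96) and CDH5 (from 6.17 to 9.20). The steps before it counted 538, 712, 744 and 913 genes, and the steps after it 270, 106 and 116. These counts rest on single arrays without a test. With the submitters' own normalized values the 8 steps held 1040, 1172, 1237, 1569, 1659, 574, 344 and 396 genes. Without background correction they held 322, 486, 521, 628, 731, 157, 65 and 68. The first principal component of the 9 arrays carried 63.0% of the variance and ordered the days from 0 to 8, and the 2nd carried 15.8%.

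**Figure D2:**
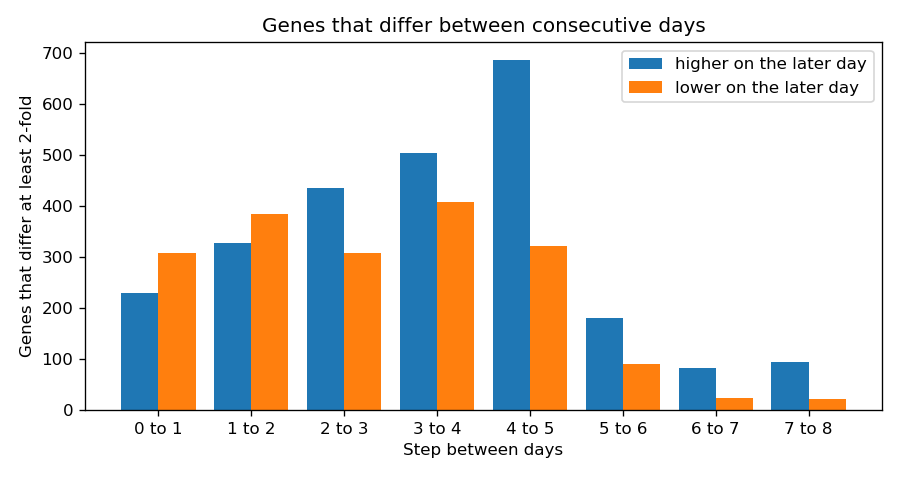
Number of genes that differed at least 2-fold between each day and the next, with bars for genes higher and lower on the later day. The step from day 4 to day 5 was the largest, with 687 genes higher and 322 lower.

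Over the first 4 days, under BMP4, VEGF, SCF and activin, genes of mesoderm appeared and genes of the undifferentiated state fell. HAND1, a transcription factor of lateral and extraembryonic mesoderm, rose by 10.68 ± 1.29 on the log2 scale (adjusted p = 0.00126) and was at least 327-fold higher on the day 4 array than on the day 0 array. APLNR, the apelin receptor of early mesoderm, rose by 9.60 ± 1.23 (adjusted p = 0.00165). Among the largest fitted rises were also HAPLN1, which links hyaluronan to proteoglycans (8.49), WLS, which is needed to secrete WNT proteins (7.43), the transcription factor IRX3 (7.60), GYPE, a glycophorin family gene (7.59), ALPK2 (7.72) and RHOBTB3 (7.36). In all, 1108 genes rose and 1046 fell. Of 14 early mesoderm genes tested, 12 rose and 12 did so adjusted over the list alone, among them PDGFRA (6.16) and SNAI2 (6.81) (camera adjusted p = 6.89e-11, adjusted p = 0.239 with an estimated correlation). Of 13 primitive streak genes, 6 rose and 7 did so adjusted over the list alone, among them EOMES (5.23), FOXA2 (4.66), MIXL1 (4.31) and LHX1 (4.30), while NODAL, a growth factor that keeps the undifferentiated state, had a fitted change of -4.13 (camera adjusted p = 0.00265, adjusted p = 0.35 with an estimated correlation). With a curve of 2 degrees of freedom the rises of EOMES, MIXL1 and LHX1 did not pass (adjusted p = 0.47, 0.611 and 0.208).

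Pluripotency genes fell together over these 4 days. Of 17 genes, 12 fell and 13 did so adjusted over the list alone, with a list median of -2.27 on the log2 scale (camera adjusted p = 1.3e-10, adjusted p = 0.203 with an estimated correlation). With the submitters' own values this median was -2.89. SOX2 (-5.22 ± 0.44), PRDM14 (-4.92 ± 0.47) and NANOG (-4.02 ± 0.47), all transcription factors of the undifferentiated state, had the largest fitted falls, followed by USP44, a ubiquitin protease (-3.56 ± 0.37). The largest fitted falls of all genes were ACTA1, a muscle actin (-7.15), the metallothioneins MT1H (-7.07) and MT1G (-6.29), and the Nodal inhibitors LEFTY1 (-6.43) and LEFTY2 (-6.32). They were followed by SPP1, which encodes osteopontin (-6.06), ACTG2, a smooth muscle actin (-5.73), and CCN1, a matrix protein (-5.70). A fitted change can differ from that between the day 0 and day 4 arrays. On those arrays ACTG2 was 20.5-fold lower on day 4, less than fitted, and LEFTY2 105-fold lower, more than fitted. Of 8 Nodal and activin pathway genes, 4 fell, and adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.0233, adjusted p = 0.33 with an estimated correlation). The parent line was kept on mouse feeder cells, and some mesenchyme genes were high on day 0: TAGLN stood at 13.32 on day 0 and 8.01 on day 3, and COL1A1 at 9.37 and 5.94 on days 0 and 2. COL3A1 (5.11) and DCN (4.45), which fibroblasts also express, were low on day 0.

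Signalling targets and HOXB genes also rose over the first 4 days. Of 9 BMP pathway targets 6 rose, also when adjusted over the list alone, led by MSX1 (6.94), SMAD6 (5.15) and ID2 (4.06) (camera adjusted p = 2.47e-05, adjusted p = 0.269 with an estimated correlation). Of 7 WNT targets 5 rose, also when adjusted over the list alone, led by DKK1 (6.52) and LEF1 (5.09) (camera adjusted p = 8.31e-05, adjusted p = 0.269 with an estimated correlation). Of 7 HOXB genes 6 rose and 7 did so adjusted over the list alone, led by HOXB5 (5.57) and HOXB2 (5.39) (camera adjusted p = 4.66e-06, adjusted p = 0.274 with an estimated correlation). Of 11 HOXA genes fewer than 4 were detected on any day, so the list was not tested, and HOXA5 had no trend that passed (adjusted p = 0.183). Of 14 endoderm genes 7 rose and 1 fell, also when adjusted over the list alone, with APOA1 (5.34) and APOA2 (4.86) up and AFP (-3.23) down (camera adjusted p = 0.000637, adjusted p = 0.203 with an estimated correlation). Of 17 blood transcription factors 5 rose and 7 did so adjusted over the list alone, among them LYL1 (3.21) and GATA2 (2.71), while BCL11A fell (-1.65) (camera adjusted p = 0.000483, adjusted p = 0.285 with an estimated correlation). Of 13 red cell genes 3 rose and 4 did so adjusted over the list alone, led by the glycophorin GYPB (6.23) and ALAS2, the enzyme that starts haem synthesis in red cells (2.07) (camera adjusted p = 0.0221, adjusted p = 0.35 with an estimated correlation). Of 12 immediate-early and stress genes JUN (-2.28) and ZFP36 (-1.34) fell, also when adjusted over the list alone (camera adjusted p = 0.042, adjusted p = 0.432 with an estimated correlation). Of 18 endothelial genes 7 rose, also when adjusted over the list alone (camera adjusted p = 0.000637, adjusted p = 0.33 with an estimated correlation). Among them were VWF (3.29) and SOX17 (4.35), which is also on the endoderm list. With a curve of 2 degrees of freedom DKK1, SOX17, AFP, JUN and ZFP36 did not pass (adjusted p = 0.0656, 0.0531, 0.478, 0.164 and 0.0582), and with a robust prior GYPB did not (adjusted p = 0.108).

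A group of genes appeared and was lost again within the 9 days. The largest transient peaks among genes with a trend were those of EOMES and MIXL1, transcription factors of the primitive streak, which on day 2 stood at least 156-fold and at least 136-fold above the higher of days 0 and 8. MESP1, a factor of nascent mesoderm (at least 81.5-fold), and TBXT, the brachyury factor of the primitive streak (at least 61.2-fold), also peaked on day 2. GRP, a peptide hormone gene (at least 109-fold), LHX1, a transcription factor (at least 30.5-fold), and LZTS1 (at least 23.5-fold) peaked on day 3. DKK1, a WNT inhibitor (at least 50.3-fold), CST1, a cystatin (34.3-fold), and FABP7, a fatty acid binding protein of neural progenitors (4.64 on the log2 scale), peaked on day 4. In all, 387 genes with a trend had a maximum between days 1 and 7 at least 2-fold above days 0 and 8, with 96 of these maxima on day 3 and 103 on day 4, and 619 genes had such a maximum when no test was asked for. The smooth curve can miss short peaks: in simulated data a 16-fold peak on day 3 alone passed the trend test in 0% of genes. Few genes were changed in that simulation, so its adjusted cut-off was stricter than in the real data.

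Between days 4 and 8, after the change to FGF2 and IGF2, embryonic globins, endothelial genes and genes of liver and yolk sac endoderm rose. HBE1, the embryonic beta-like globin, rose by 8.69 ± 0.90 on the log2 scale (adjusted p = 0.000704) and was at least 268-fold higher on the day 8 array than on the day 4 array. HBZ, the embryonic alpha-like globin, rose by 7.67 ± 0.96 (adjusted p = 0.00189), and the fetal globins HBG1 and HBG2, which also rose, were at least 217-fold and at least 219-fold higher. TTR, a thyroid hormone carrier, rose by 8.08 ± 0.89 (adjusted p = 0.000982), and the plasma protein genes SERPINA1 (8.67), AHSG (8.26) and APOA4 (7.14) were also among the 8 largest rises. In all, 872 genes rose and 466 fell. The number that fell depended on single days and was 288 without day 7 and 308 without day 5.

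Of 14 endoderm genes 9 rose between days 4 and 8, and adjusted over the list alone 9 rose and 1 fell, with AFP (6.20) and APOB (6.09) among those that rose (camera adjusted p = 1.32e-08, adjusted p = 0.0469 with an estimated correlation). Of 13 red cell genes 7 rose, also when adjusted over the list alone, among them HBA2 (6.76) and ALAS2 (3.58) (camera adjusted p = 5.02e-07, adjusted p = 0.213 with an estimated correlation). Of 18 endothelial genes 10 rose, and adjusted over the list alone 11 rose and 1 fell, with CD34 (3.78 ± 0.51), PECAM1 (2.53 ± 0.53) and CDH5, the endothelial cadherin (2.37 ± 0.49), among those that rose (camera adjusted p = 1e-06, adjusted p = 0.269 with an estimated correlation). Of 14 mesenchyme genes 7 rose and 8 did so adjusted over the list alone, led by DCN (5.18) and COL3A1 (4.22) (camera adjusted p = 4.74e-06, adjusted p = 0.239 with an estimated correlation). Of 8 leukocyte genes 3 rose and 4 did so adjusted over the list alone, led by ARHGDIB (4.07) (camera adjusted p = 0.00264, adjusted p = 0.269 with an estimated correlation). Of 9 myeloid genes 4 rose and 1 fell, also when adjusted over the list alone, with AIF1 (1.68) the largest rise and S100A9 (-1.27) the fall (camera adjusted p = 0.00785, adjusted p = 0.269 with an estimated correlation). Of 12 immediate-early and stress genes, a list that fell from day 0 to day 4, 1 rose in this interval, also when adjusted over the list alone, and the list shifted up (camera adjusted p = 0.025, adjusted p = 0.397 with an estimated correlation). Without day 7 PECAM1, CDH5, ARHGDIB and S100A9 did not pass (adjusted p = 0.109, 0.119, 0.1 and 0.129), and with the submitters' own values COL3A1 did not (adjusted p = 0.0577). Of the 6 megakaryocyte genes tested none changed in this interval, and their median was 0.34 (camera adjusted p = 0.372, adjusted p = 0.54 with an estimated correlation).

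Genes of proliferation and of the primitive streak fell between days 4 and 8. Of 15 cell cycle genes 9 fell, also when adjusted over the list alone, among them the ribonucleotide reductase subunit RRM2 (-1.69 ± 0.32), the mitotic kinase AURKB (-1.59 ± 0.27) and the replication factor MCM5 (-1.58 ± 0.26) (camera adjusted p = 2.63e-10, adjusted p = 0.203 with an estimated correlation). Of 13 primitive streak genes 3 fell and 6 did so adjusted over the list alone (camera adjusted p = 8.31e-05, adjusted p = 0.285 with an estimated correlation). Of 17 pluripotency genes 6 fell and 8 did so adjusted over the list alone, led by POU5F1 (-3.50 ± 0.23) (camera adjusted p = 4.75e-06, adjusted p = 0.269 with an estimated correlation). Of 7 WNT targets 2 fell and 4 did so adjusted over the list alone (camera adjusted p = 0.0129, adjusted p = 0.35 with an estimated correlation). Among the largest fitted falls of all genes were EOMES (-5.19), DKK1 (-4.83), the zinc finger factor ZIC2 (-4.08), CHGA, a secretory granule protein (-4.08), MIXL1 (-4.07), POU5F1 and OLFM1 (-3.45). The falls of DKK1, CHGA and OLFM1 did not pass without day 7 (adjusted p = 0.127, 0.0809 and 0.0738). Those of EOMES and MIXL1 did not pass with a curve of 2 degrees of freedom (adjusted p = 0.0588 and 0.0881).

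By day 8 pluripotency genes had fallen and mesoderm, endothelial, endoderm and red cell genes had risen above day 0. Across the whole course 2077 genes rose and 1809 fell. HAND1 had the largest fitted rise (10.49, adjusted p = 0.00137), followed by APOA2, an apolipoprotein (9.81 ± 0.98), HBE1 (9.43), HBG2 (9.02), HBG1 (8.91), TTR (8.80), SERPINA1 (8.64) and APOA1 (8.55). LEFTY2 (-8.49 ± 0.98, adjusted p = 0.000508) and LEFTY1 (-7.75) had the largest fitted falls, followed by MT1H (-7.23), SOX2 (-7.16), MT1G (-6.79), UCA1, a long noncoding RNA (-6.57), VGF, a neuropeptide precursor (-6.40), and POU5F1 (-6.36). Of 17 pluripotency genes 16 fell, also when adjusted over the list alone, and LIN28B, an RNA-binding protein, had a fitted change of 0.53 ± 0.23 that did not pass (camera adjusted p = 7.55e-11, adjusted p = 0.203 with an estimated correlation). Of 18 endothelial genes 14 rose and 15 did so adjusted over the list alone (camera adjusted p = 5.85e-08, adjusted p = 0.269 with an estimated correlation). Of 13 red cell genes 9 rose and 11 did so adjusted over the list alone (camera adjusted p = 1.13e-07, adjusted p = 0.203 with an estimated correlation). Of 14 endoderm genes 11 rose and 12 did so adjusted over the list alone (camera adjusted p = 9.07e-09, adjusted p = 0.0469 with an estimated correlation). Of 14 mesenchyme genes 9 rose, among them LUM (8.36) and COL3A1 (7.55), and TAGLN, TWIST2 and THY1 fell, and adjusted over the list alone 10 rose and 3 fell (camera adjusted p = 0.000861, adjusted p = 0.274 with an estimated correlation). Without day 7 the fall of THY1 did not pass (adjusted p = 0.0539).

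Mesoderm, HOXB and BMP target genes, which rose by day 4, were still above day 0 on day 8. Of 14 early mesoderm genes 10 rose and 11 did so adjusted over the list alone (camera adjusted p = 3.84e-06, adjusted p = 0.285 with an estimated correlation). Of 7 HOXB genes 6 rose, also when adjusted over the list alone (camera adjusted p = 0.000132, adjusted p = 0.307 with an estimated correlation). Of 9 BMP targets 6 rose, also when adjusted over the list alone (camera adjusted p = 0.00158, adjusted p = 0.308 with an estimated correlation). Of 17 blood transcription factors 7 rose and 1 fell, led by LYL1 (4.54) and LMO2 (4.24), and adjusted over the list alone 8 rose and 1 fell (camera adjusted p = 0.000433, adjusted p = 0.285 with an estimated correlation). Of 8 Nodal and activin genes 5 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0107, adjusted p = 0.308 with an estimated correlation). Of 8 leukocyte genes 5 rose and 1 fell, and adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.0114, adjusted p = 0.27 with an estimated correlation). Of 15 cell cycle genes 8 fell, also when adjusted over the list alone (camera adjusted p = 0.000109, adjusted p = 0.269 with an estimated correlation). Of 14 arterial and Notch genes 3 rose, NRP1, GJA4 and NOTCH1, and HEY2 fell, and adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.0817, adjusted p = 0.276 with an estimated correlation). Of 5 venous genes NR2F2 alone rose (3.14), also when adjusted over the list alone (camera adjusted p = 0.296, adjusted p = 0.432 with an estimated correlation). Of 7 heart muscle genes 2 rose, MYL4 (6.77) and MYL7 (4.26), also when adjusted over the list alone (camera adjusted p = 0.193, adjusted p = 0.62 with an estimated correlation). Of 8 trophoblast and surface ectoderm genes, CDX2 (4.44) and GATA3 (2.05) rose and TFAP2C (-2.23) fell, and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.135, adjusted p = 0.308 with an estimated correlation). Of 7 neural progenitor genes LHX2 rose and SOX3, HESX1 and OTX2 fell, also when adjusted over the list alone (camera adjusted p = 0.153, adjusted p = 0.324 with an estimated correlation). Of 10 hypoxia genes 3 rose, NDRG1, VEGFA and BNIP3, and ADM and EGLN3 fell, also when adjusted over the list alone (camera adjusted p = 0.178, adjusted p = 0.62 with an estimated correlation). Of 12 immediate-early and stress genes KLF2 rose and JUN fell, and adjusted over the list alone 1 rose and 0 fell (camera adjusted p = 0.928, adjusted p = 0.978 with an estimated correlation). Without day 7 NOTCH1, LHX2 and OTX2 did not pass (adjusted p = 0.0796, 0.0647 and 0.0928), without day 1 MYL7 and JUN did not (adjusted p = 0.0726 and 0.119), and with a curve of 2 degrees of freedom HEY2 did not (adjusted p = 0.078).

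Of the 72 list tests over days 35 passed with the preset correlation, and with an estimated correlation 2 did, the rises of the endoderm list from day 4 to day 8 and from day 0 to day 8. The self-contained test fry, which asks only whether a list's genes move on balance one way, passed in 39. Median, mean and test differed in sign for the primitive streak list from day 0 to day 8 (median 0.09, mean -0.15), for the neural progenitor list from day 0 to day 4 (median 0.38, mean -0.36), for the hypoxia list from day 4 to day 8 (median -0.16, mean 0.08) and for the trophoblast list from day 4 to day 8 (median -0.08, mean 0.05). None of these 4 passed with camera, and the neural progenitor list passed with fry as a fall (adjusted p = 0.00699). The same was seen in the megakaryocyte list from day 0 to day 4, the cardiac list from day 4 to day 8 with fry, and the reference genes in each interval, all with adjusted p of at least 0.928 by camera.

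The sorted fractions asked how cells that carry CD34 or CD41 on day 7 differ from each other. CD34 RNA followed the sort, at 8.52 in CD34- CD41-, 10.58 in CD34lo CD41-, 12.88 in CD34hi CD41- and 10.06 in CD34lo CD41lo. ITGA2B was 4.70, 5.96, 5.26 and 9.19 in the same order, and detected in CD34lo CD41- and CD34lo CD41lo. RUNX1 was not detected in CD34- CD41- and stood at 8.20, 8.70 and 9.71 in the other fractions. With 1 array per fraction no test could be run, so genes are called higher or lower by a rule of at least 2-fold among 15891 genes. Percentiles give the place of a list's median among 10000 random lists of like expression and describe these arrays only.

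**Figure D3:**
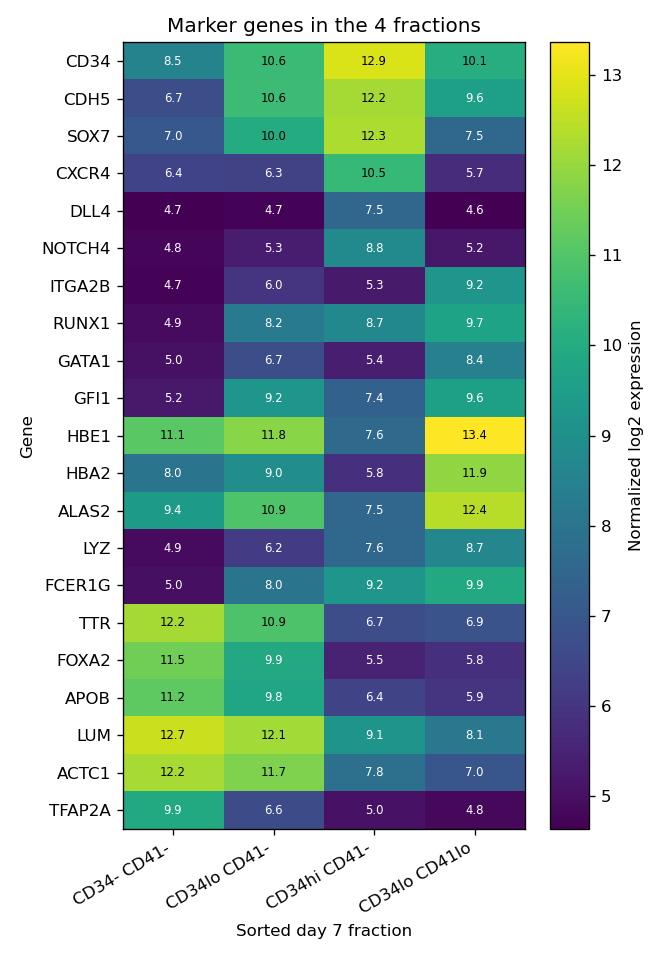
Normalized log2 expression of 21 marker genes, in rows, in the 4 sorted day 7 fractions, in columns, 1 array each, with the value printed in each cell. CD34 and CDH5 were highest in CD34hi CD41- (12.88 and 12.19), ITGA2B and HBE1 in CD34lo CD41lo (9.19 and 13.36), and TTR and FOXA2 in CD34- CD41- (12.18 and 11.46).

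CD34lo CD41- cells had more RNA of endothelial and early blood genes than CD34- CD41- cells. ICAM2, an adhesion molecule of endothelium (19.6-fold), F2RL2, a thrombin receptor (17.7-fold), GFI1, a repressor in blood stem cells (at least 15.2-fold), and CDH5 (14.5-fold) were among the 8 genes with the largest differences upward, with SCGN (15.9-fold), ECSCR (15.2-fold) and PRKCB (13.8-fold). TFAP2A (9.89-fold) and TFAP2C (6.04-fold), factors of surface ectoderm and trophoblast, DLX5 (at least 7.17-fold), TRIML2 (6.13-fold), the retrogene POU5F1B (5.22-fold) and CDH1, the epithelial cadherin (4.85-fold), were lower. In all, 420 genes were higher and 672 lower (108 and 15 by 4-fold), and 676 were higher with the submitters' own values. Of 18 blood transcription factors 14 were higher, with a list median of 4.45-fold (percentile 100). Of 21 endothelial genes 13 were higher and 1 lower, with a list median of 3.46-fold (percentile 100). Of 13 endoderm genes 8 were lower and none higher (median -1.34 on the log2 scale, percentile 0).

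CD34hi CD41- cells carried the endothelial genes at their highest level. Against CD34- CD41- cells, 19 of 21 endothelial genes were higher, with a list median of 15.8-fold (percentile 100), among them CDH5 (43.4-fold) and the receptor TIE1 (at least 42.1-fold). On the log2 scale this median was 3.99, and 3.33 without background correction. Of 15 arterial and Notch genes 13 were higher, with a list median of 4.66-fold (percentile 100), among them the chemokine receptor CXCR4 (17.2-fold), NOTCH4 (at least 11.6-fold) and the Notch ligand DLL4 (at least 4.66-fold). Of 4 venous genes 3 were higher (percentile 99.8). ADGRF5, an adhesion receptor of endothelium (53.0-fold), FAM124B (at least 50.8-fold), CD300LG (44.7-fold), CD93 (42.7-fold), F2RL2 (44.6-fold) and ECSCR (44.7-fold) completed the 8 largest differences upward. FOXA2, a pioneer factor of endoderm (64.4-fold), KCNK12 (57.0-fold), OVOL2 (at least 50.3-fold), MTTP, which loads lipid onto lipoproteins (47.9-fold), RSPO3, a WNT agonist (45.3-fold), TTR (44.9-fold), FGA (at least 44.8-fold) and FGB (43.8-fold), which encode fibrinogen chains, were lower by the most. Of 13 endoderm genes 11 were lower (percentile 0), and of 15 red cell genes 7 were lower and 1 higher (percentile 0.0650). Of 18 blood transcription factors 9 were higher and 2 lower (median 2.78-fold, percentile 100), of 9 leukocyte genes 5 were higher and 1 lower (4.03-fold, percentile 100), and of 9 myeloid genes 5 were higher and none lower (2.63-fold, percentile 100). The myeloid median was 1.40 on the log2 scale, and 2.11 with the submitters' own values. In all, 1112 genes were higher and 1415 lower (380 and 444 by 4-fold).

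CD34lo CD41lo cells carried most blood genes at higher levels than CD34- CD41- cells. Against CD34- CD41- cells, 15 of 18 blood transcription factors were higher and 1 lower, with a list median of 8.83-fold (percentile 100), among them RUNX1 (at least 21.4-fold), GFI1 (at least 19.6-fold) and MYB, a factor of blood progenitors (16.8-fold). Of 7 megakaryocyte genes 6 were higher (median 6.84-fold, percentile 100), and 14 of 15 red cell genes (4.71-fold, percentile 100), 7 of 9 leukocyte genes, with 1 lower (4.78-fold, percentile 100), and 6 of 9 myeloid genes (10.4-fold, percentile 100) were higher too. On the log2 scale the myeloid median was 3.38, and 2.76 without background correction, and the leukocyte median was 2.26, and 3.11 with the submitters' own values. Among the largest differences upward were HBBP1, a globin pseudogene (at least 45.0-fold), HBD, the delta globin (at least 36.9-fold), TIMP3, a protease inhibitor (35.5-fold), FERMT3, which activates integrins in platelets (at least 33.9-fold), LY6G6D (at least 29.2-fold), PTGS1, a cyclooxygenase of platelets (27.6-fold), and MS4A3 (25.9-fold). Of 15 cell cycle genes 11 were higher (median 2.97-fold, percentile 100). Of 13 endoderm genes 12 were lower and of 13 mesenchyme genes 10 were lower (percentile 0 and 0), with KCNK12 (50.7-fold), FOXA2 (50.6-fold), OVOL2 (47.4-fold), FGB (6.97 against 12.33), TTR (39.8-fold), ACTC1, the cardiac actin (38.6-fold), APOB (38.6-fold) and AKR1B10 (37.5-fold) the largest differences downward. In all, 1312 genes were higher and 1756 lower (256 and 580 by 4-fold).

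CD34hi CD41- cells also had more endothelial and less globin and endoderm RNA than CD34lo CD41- cells. LPL, lipoprotein lipase (28.6-fold), GIMAP4 (22.1-fold), CD300LG (20.3-fold), ADGRF5 (18.3-fold), CXCR4 (18.2-fold), A2M, a protease inhibitor (18.0-fold), PRND (at least 17.6-fold) and CLDN5, a tight junction protein (at least 16.3-fold), were higher by the most. HBZ (27.6-fold), FOXA2 (21.8-fold), RSPO3 (20.7-fold), APOA2 (19.0-fold), TTR (18.9-fold), HBE1 (18.0-fold), MTTP (17.9-fold) and AKR1B10 (at least 17.7-fold) were lower by the most. Of 21 endothelial genes 19 were higher (percentile 100), of 15 arterial and Notch genes 12 were higher (percentile 100), and of 15 red cell genes 11 were lower (percentile 0). Of 18 blood transcription factors 2 were higher, among them MECOM (7.41-fold), and 8 lower, among them GFI1 (3.64-fold) (percentile 0.04). In all, 633 genes were higher and 636 lower (148 and 178 by 4-fold).

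Against CD34lo CD41- cells, CD34lo CD41lo cells had more RNA of red cell genes, globins among them, and of CD41. HBD (21.3-fold), HBBP1 (16.6-fold), ITGA2B (9.40-fold), HBA1 (8.40-fold), HBA2 (7.74-fold), the adult beta globin HBB (6.43-fold), the theta globin HBQ1 (6.24-fold) and LYZ, the lysozyme of myeloid cells (5.74-fold), were higher by the most. ACTC1 (25.9-fold), APOA2 (20.6-fold), FOXA2 (17.1-fold), TTR (16.8-fold), CST1 (16.7-fold), HTRA1, a serine protease (at least 16.5-fold), AKR1B10 (16.3-fold) and LUM, a matrix proteoglycan (16.1-fold), were lower by the most. In this comparison 13 of 15 red cell genes (percentile 100), 6 of 7 megakaryocyte genes (percentile 100), and 6 of 9 myeloid genes (percentile 100) were higher. Of 18 blood transcription factors 8 were higher and 2 lower (percentile 100). Of 13 mesenchyme genes 11 were lower (percentile 0). Of 13 endoderm genes 10 were lower and none higher, with a list median 13.3-fold lower (percentile 0). In all, 426 genes were higher and 902 lower (20 and 282 by 4-fold), and the number higher was 272 without background correction and 816 with the submitters' own values.

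CD34lo CD41lo and CD34hi CD41- cells parted along blood and endothelial genes. HBZ (78.2-fold), HBA2 (66.9-fold), HBE1 (53.0-fold), HBBP1 (at least 42.0-fold), HBD (at least 34.5-fold), ALAS2 (30.5-fold), HBA1 (at least 30.5-fold) and HBG2 (13.82 against 8.91) were higher in CD34lo CD41lo by the most. ADGRF5 (32.4-fold), GIMAP4 (32.0-fold), TM4SF18 (29.7-fold), CXCR4 (27.2-fold), SOX7, an endothelial transcription factor (26.9-fold), CD300LG (26.5-fold), the tetraspanin CD9 (at least 25.2-fold) and MECOM, a regulator of blood stem cells (22.9-fold), were lower by the most. Of 21 endothelial genes 20 were lower (percentile 0), of 15 arterial and Notch genes 13 were lower (percentile 0), and of 15 red cell genes 13 were higher (percentile 100). RUNX1 was 2.01-fold higher in CD34lo CD41lo (9.71 against 8.70). This lay at the limit of the rule, with a log2 difference of 0.99 when each chip was normalized alone and 0.96 without background correction. Of 18 blood transcription factors 12 were higher in CD34lo CD41lo and 2 lower, and of 7 megakaryocyte genes 4 were higher and 1 lower. Leukocyte and myeloid genes differed less: 4 of 9 and 3 of 9 were higher, with list medians of 1.54-fold and 1.55-fold. Of 15 cell cycle genes 5 were higher in CD34lo CD41lo (percentile 100). In all, 821 genes were higher and 1105 lower (112 and 367 by 4-fold).

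CD34- CD41- cells carried endoderm, mesenchyme, heart muscle and signalling target genes at higher levels than CD34lo CD41lo cells. Of 9 BMP targets 6 were lower in CD34lo CD41lo, among them ID3 (5.09-fold) and MSX1 (8.82-fold) (percentile 0), and 5 of 7 WNT targets were lower, among them SP8 (27.0-fold) and AXIN2 (10.7-fold) (percentile 0.05). Of 8 hypoxia genes 5 were lower, among them ADM (11.7-fold) (percentile 0.03), and of 13 early mesoderm genes 8 were lower and 1 higher (percentile 0). Of 8 HOXB genes 4 were lower, among them HOXB8 (8.97-fold) (percentile 0.28), and no HOXA gene was detected in any fraction. Of 6 heart muscle genes 3 were lower and MYL4, a myosin light chain of embryonic muscle and atrium, was higher (2.90-fold, percentile 0.11). Of 5 neural progenitor genes 3 were lower (percentile 0.01), of 6 trophoblast and surface ectoderm genes 4 were lower (percentile 0), and of 5 primitive streak genes 2 were lower (percentile 8.87). Of 10 pluripotency genes 3 were lower, and GDF3, a growth factor of the undifferentiated state, was higher (at least 6.91-fold, percentile 6.43), and of 4 Nodal and activin genes 1 was higher and 1 lower (percentile 61.5). Of 12 immediate-early and stress genes 4 were lower and 1 higher (percentile 7.76), and of 12 reference genes HPRT1 alone was higher (2.76-fold, percentile 66.5).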

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

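Of the alternatives, a spline of 5 degrees of freedom was chosen after the results were seen, and the others before. Each result was run under those of the 22 settings that apply to it, and no named gene that passed turned its direction. The genes higher and lower in CD34hi CD41- than in CD34lo CD41- were nearly equal in number, and which were more turned: 633 and 636, against 486 and 480 without background correction, 616 and 596 with the mean of a gene's probes, and 901 and 864 with the submitters' normalized values. From day 0 to 4 it turned too, from 1108 and 1046 to 1005 and 1031 without day 1 and 856 and 868 without day 3. Leaving out 1 day at a time gave 5247 to 6863 genes with a trend, 856 to 1188 higher and 868 to 1057 lower from day 0 to 4, 597 to 994 higher and 288 to 616 lower from day 4 to 8, and 1833 to 2118 higher and 1582 to 1891 lower from day 0 to 8. Leaving out day 0 or day 8 gives no value for changes that start or end there. The lowest number lower from day 4 to 8 came without day 7, and without day 5 it was 308. Day 5 and day 7 lie inside the interval, and the cause was not tested. With 5 degrees of freedom 5860 genes had a trend, 1329 were higher and 1164 lower from day 0 to 4, 1026 and 660 from day 4 to 8, and 2159 and 1907 from day 0 to 8, and with 2 and 4 degrees of freedom 6768 and 6680 genes had a trend. Of 35 list calls 2 were left with an estimated correlation.

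Counts without a test depended on how weak signals were treated. The size of list medians depended on it too: of 216 medians, 15 crossed 2-fold without background correction and 17 with the submitters' normalized values. Signal over background limits what can be seen in genes of low expression. Without the detection floor, 909 genes differed from day 0 to 1, 1200 from day 1 to 2, 173 from day 6 to 7 and 179 from day 7 to 8. Without background correction, 322 differed from day 0 to 1, 157 from day 5 to 6, 65 from day 6 to 7 and 68 from day 7 to 8, and 272 genes were higher in CD34lo CD41lo than in CD34lo CD41-. With the submitters' normalized values the steps from day 0 on held 1040, 1172, 1237, 1569, 1659, 574, 344 and 396 genes, 676 genes were higher in CD34lo CD41- than in CD34- CD41-, and 816 were higher in CD34lo CD41lo than in CD34lo CD41-.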

Other observations

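Glycophorin genes, which encode red cell surface proteins, came on days before the globins. GYPB stood at 4.54 on day 2 and 10.75 on day 3, and GYPE at 6.62 and 12.06, while HBE1 stood at 6.19 on day 5 and 10.73 on day 6. HOXB genes rose while most HOXA genes were not detected: HOXB5 stood at 5.24 on day 0 and 11.33 on day 4, and HOXA5 at 7.32 on day 1 and 4.40 on day 8, where it was not detected. DCN and POSTN, matrix genes of mesenchyme, stood at 12.26 and 9.48 in unsorted day 7 cells, and their highest levels in the sorted fractions of the other experiment were 8.52 and 5.78.

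The tests below were chosen after the patterns were seen, except for the order of the days and the mixture. Genes with a trend depend on the order of the days: 1 of 100 orders, the real one included, gave as many. The other orders had a median of 0 such genes, with none in 97 orders, and the highest number was 5158. No biological explanation was tested for this count.

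CD34lo CD41- cells lay between the other fractions, with 0% of 15891 genes at least 2-fold outside their range, against 5.34% for CD34- CD41-, 3.62% for CD34hi CD41- and 4.00% for CD34lo CD41lo. These shares rest on the brightest probe per gene and on the detection floor. Without the floor, 2 of 20495 detected probes lay at least 2-fold outside for CD34lo CD41- (largest excess 1.08 on the log2 scale). For the other fractions 841 to 1128 probes did. A mixture of cells of the other 3 fractions, through overlapping sort gates for example, could give this position between them, and an intermediate cell state would give it too. An average of the other arrays would have lowered the noise, but the SD of undetected probes was 6.71 on this array against 6.11 to 7.17 on the others.

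Globin RNA was present in CD34- CD41- cells, where HBE1, HBZ, HBG1 and HBG2 kept at least 21.1% of their CD34lo CD41lo level, and HBA1 and HBA2 as little as 5.87%. Other blood genes were counted where 21.2% of their CD34lo CD41lo level, the globin median, would exceed the CD34- CD41- detection floor. Undetected genes were set to the floor, so their shares are upper limits, which this choice holds near 21.2% or below. Of 34 such genes, 18 of them detected in CD34- CD41-, the median share was 8.24% (upper quartile 13.1%). Among them LCP1 (219%), CD68 (163%), ZFPM1 (55.6%) and SPN (26.6%) kept more than 21.1%. Of red cell genes ALAS2, KLF1, GYPB and RHAG kept 11.9%, 7.88%, 6.49% and 3.61%, and EPOR kept 88.0%. AHSP, EPB42 and ANK1, not detected there, kept at most 35.4%, 33.9% and 25.2%. Carried-over CD34lo CD41lo cells bring all their RNAs. Most of the blood gene shares lay below 21.1%, also among the genes detected in CD34- CD41-. This argues against carried-over CD34lo CD41lo cells as the whole source for the 4 globins. HBA1 and HBA2 stand as carry-over would give. Carry-over of CD34lo CD41- cells was not tested, and in those cells HBZ and HBE1 stood 27.6-fold and 18.0-fold above CD34hi CD41- cells. HBE1, HBG1 and HBG2 stood near the top of the scale, which could raise their share, but HBZ (12.50 against 14.02 for the highest probe) did not. The globins were higher in CD34- CD41- than in CD34hi CD41- by a median of 2.67 on the log2 scale, and HBA1 by 1.10. This argues against free globin RNA spread evenly over all fractions. Free RNA in unequal amounts was not tested.

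Some immediate-early genes were higher in the sorted fractions than in unsorted day 7 cells. From the list of 12, 5 genes were chosen after the pattern was seen. Of these FOS, FOSB, EGR1 and DUSP1, 4 in all, were higher in every fraction than on every unsorted day, and JUN was not. The list members left out, JUNB, IER2, ZFP36, KLF2, ATF3, HSPA1A and HSPA1B, were not either. ATF3, HSPA1A and HSPA1B had mean differences from unsorted day 7 of -1.34, -0.90 and -0.82. The reference genes differed by a median of 0.0926 on the log2 scale against 1.03 for the list of 12. The arrays of both chips were quantile normalized jointly, which removes an overall scale difference between chips beforehand. The reference genes therefore cannot test for such a difference. Dissociation and sorting cannot be told apart from a difference between the experiments, which used different chips.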
